A study of Mus musculus with 10 samples.

How the data were processed

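Total RNA was measured by sequencing in the distal ileum of 10 male diet-induced obese C57BL/6J mice, 5 gavaged with taurodeoxycholic acid (TDCA) and 5 with water. Per the labels' protocols, about 20 mg of frozen tissue per mouse went to RNA extraction, and libraries were made with a kit that depletes ribosomal RNA (Zymo-Seq RiboFree). Per the submitters' processing notes, DESeq2 1.28.0, MultiQC 1.9 and the mouse genome build GRCm39 were used. The aligner, the read counter, its handling of strand and shared reads, and the annotation are not given in the sources used here.

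The authors deposited 2 tables. The first holds normalized counts per gene, which here are treated as a signal: read counts divided by a size factor per library, by the authors. Within a library, 100% of these values were whole multiples of its smallest value above 0, within a tolerance of 1e-04 of a read, so whole reads were recovered by dividing by that step. The second table is the authors' comparison of treatment with control. Per the file headers, it gives the mean signal over the 10 libraries, a log2 fold change with its standard error, a shrunken log2 fold change, a test score (the Wald statistic), a p-value and an adjusted p-value. Its mean signal equalled the row mean of the first table. Its columns named Treatment and Control did not equal the group means, their origin is not stated, and they were not used here. Gene symbols were taken from the deposited comparison table. All 10 columns of per-library values were tied to a labelled sample, leaving 0 unmapped.

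The recovered reads summed to between 27349003 and 44342245 per library. A share of the reads of one library has an exact 95% Clopper-Pearson interval, and a gene with no read in a library is limited to 3 reads there, which is 2.57 to 3.60 normalized counts. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

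Groups were taken from the labels. Genes with a normalized count of at least 10 in at least 5 of the 10 libraries were tested, 17507 of 42989. The main test was limma-trend with robust moderation (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on that log2 scale and understate the change of low genes. Lower and higher values refer to TDCA relative to water throughout. The design was written on the assumption that the values were normalized and not raw counts, and that was what the tables held. Tests on whole reads were therefore alternatives: the edgeR quasi-likelihood test (edgeR 4.0.16), DESeq2 (version 1.42.0) and limma-voom. DESeq2 run here on the recovered reads gave an adjusted p that differed from the authors' table by more than 0.001 for 0 genes.

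Before the data were examined, 44 gene lists were fixed for ileal pathways, cell types, sampling position and tissue handling, and the rule for naming genes was fixed too. Lists with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 43 lists tested. Camera with an estimated correlation and fry were run beside it. A list score is the mean over its members of the log2 level, centred per gene, and scores and single values were compared by two-sided exact permutation over the 252 labelings of 5 against 5, whose smallest p is 0.00794. Members were also counted after adjustment over the list alone. Genes are named if they were among the 5 per direction with the smallest p in limma (mean of at least 50 normalized counts), because no gene passed; if they were 1 of 8 fixed bile acid genes; if they were among the 4 members with the smallest p of a list that passed, or the 2 of another list; or if they were among the 5 per direction with the smallest adjusted p in the authors' table. Predicted gene models were not named.

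Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of 50, TMM and quantile normalization, moderation without robustness, array weights, the tools named above, the replicate number as a block, leaving out each library in turn, and an adjusted p under 0.10. After the data were seen, fits without water 1 and TDCA 5, fits with the smooth muscle score as a covariate, the exact permutation of list scores, and DESeq2 with libraries left out were added. The lengths of transcripts came from GENCODE M21, matched by gene identifier without its version, for 99.4% of the tested genes. That annotation belongs to GRCm38 and not to the build in the notes, so no coordinates are printed.

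The main limma test, DESeq2, edgeR and camera with the preset correlation were run first on simulated counts. The other tests were not. The counts had the real genes' means and library sizes. The 200 changed genes were drawn from those with a mean of at least 50 normalized counts. For TDCA against water over 17271 genes, limma called 68% of genes changed 2-fold and 98% of those changed 4-fold, with 4.60% of its calls unchanged genes. DESeq2 called 82% and 99%, with 15.4% of its calls unchanged genes, and edgeR called 71% and 97%, with 4.55%. In a separate simulation without changed genes, camera called 0 lists. The simulated genes varied independently of each other, so this does not test the preset correlation on genes that vary together. For the same reason the shares of changed genes called may not hold in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.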

Results

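Total RNA depleted of ribosomal RNA was sequenced from the distal ileum, the last stretch of the small intestine and the main site of conjugated bile acid uptake, of 10 male C57BL/6J mice made obese by diet. At 10 weeks of age the mice began 4 weeks of oral gavage. In 5 mice the gavage held taurodeoxycholic acid (TDCA), a taurine-conjugated secondary bile acid, at 10 mg per kg body weight, and in 5 it was water. Replicates are called water 1 to water 5 and TDCA 1 to TDCA 5. The libraries held 37395629, 33274828, 27349003, 33943382 and 44342245 reads on genes in water 1 to 5, and 40972956, 35051797, 44057560, 40756958 and 35312794 reads in TDCA 1 to 5, with no difference in mean beyond the spread (two-sided exact permutation p = 0.294). At least 1 read was found for 25381 to 31865 genes per library. The 2 mitochondrial ribosomal RNAs took 30.2% of the reads in water 3 (exact 95% interval 30.2 to 30.2%) and 40.5 to 48.1% in the other 9 libraries. Their share was 43.4% ± 7.45 in water and 43.3% ± 1.93 in TDCA libraries (SD, n = 5 each, exact permutation p = 0.992).

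Pairs of libraries had a Spearman correlation across genes of 0.946 to 0.984, genes not being independent replicates. The first principal component held 28.5% of the variance, with water 1 at one end (−70.3) and TDCA 5 at the other (56.8), and its group means did not differ beyond the spread (exact permutation p = 0.103). A measure of RNA composition differed between the groups. In each library the level of a gene, centred over libraries, was correlated with the length of its transcript across genes. This Spearman correlation averaged −0.10 ± 0.05 in water and 0.07 ± 0.07 in TDCA libraries (SD, n = 5 each, two-sided exact permutation p = 0.0159), so long transcripts were relatively higher in the TDCA libraries. Across genes, length and the log2 fold change had a Spearman correlation of 0.191.

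The comparison of TDCA with water asks which ileal transcripts differ after 4 weeks of the bile acid, in a series whose title concerns a small intestinal bile acid, gut microbes and metabolism after weight-loss surgery. Tested as groups with a preset correlation between genes, products of Paneth cells, the antimicrobial cells at the base of the crypts, were lower in TDCA ilea, as were cell-cycle genes, but with an estimated correlation 0 groups passed (smallest adjusted p = 0.626). In the same test smooth muscle genes were higher (mean log2 fold change 0.70, and 0.36 without both water 1 and TDCA 5), likewise not with an estimated correlation (adjusted p = 0.649). The single gene with the smallest p was Defa24 (ENSMUSG00000064213), an α-defensin, at 2981 ± 669 normalized counts in TDCA against 5998 ± 1163 in water mice (SD, n = 5 each). No single gene passed limma's test.

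Of 17507 genes tested, limma called 0 at an adjusted p under 0.05, the smallest adjusted p being 0.448. At an unadjusted p under 0.05 there were 1919 genes, 1042 higher and 877 lower, where chance alone gives 875 on average. Among 100 splits of the 10 libraries into 5 and 5, the real one included, 7 gave a count as large (highest other 3249). The edgeR quasi-likelihood test called 0 genes (1755 unadjusted), limma-voom 0 (1918 unadjusted) and DESeq2 25 (2214 unadjusted). The ranges of the groups did not overlap for 245 genes (1.40%), and chance gives 0.794%. The median log2 fold change over all tested genes was −0.01.

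The lower genes with the smallest p in limma did not pass (adjusted p = 0.448 for each). Among them were Defa24 (log2 fold change −1.01, SE 0.18), Ang4, a ribonuclease of Paneth cells (−1.01, SE 0.18), Defa26 (−1.07, SE 0.20) and the adhesion receptor gene Adgrg4 (−0.93, SE 0.19). The 5 higher genes with the smallest p, with the same adjusted p, were the δ-sarcoglycan gene Sgcd (0.66, SE 0.15), the sodium-calcium exchanger gene Slc8a1 (0.72, SE 0.16), Mfap3l (0.85, SE 0.20), the metalloproteinase gene Pappa (0.70, SE 0.16) and the dynein gene Dnah5 (0.89, SE 0.21). Of these genes, all but Sgcd had ranges without overlap between the groups (exact permutation p = 0.00794, the smallest possible, against 0.0159 for Sgcd). They were chosen by the smallest p on these same libraries, so this separation is not further support.

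The authors' deposited table, made with DESeq2, lists 25 genes at an adjusted p under 0.05 among 13800 with one, 3 higher and 22 lower in TDCA mice. The lower genes with the smallest adjusted p there were Defa24 (log2 fold change −1.01, adjusted p = 0.00192), the glutathione S-transferase gene Gstm3 (−4.46, adjusted p = 0.00363), Defa26 (−1.11, adjusted p = 0.00363), Ang4 (−0.98, adjusted p = 0.00363) and Olfm4, a glycoprotein gene of crypt base cells (−1.61, adjusted p = 0.00429). The higher genes were Trdn, which encodes triadin of the muscle calcium store (1.54, adjusted p = 0.0395), Slc8a1 (0.70, adjusted p = 0.0418) and Sgcd (0.64, adjusted p = 0.0479). Of these 25 genes, all had the same sign in limma with an unadjusted p of at most 0.00853 (largest), and 14 had ranges without overlap. Both tests used the same libraries, so this is not independent support. Across 13793 genes the fold changes of the table and of limma had a Pearson correlation of 0.958 and a Spearman correlation of 0.980, genes not being independent replicates. Members of the Paneth list were called more often than other genes there, 4 of 15 (Fisher's exact test, one-sided, adjusted p = 4.62e-07 over 41 lists). That test treats genes as independent, which near-identical α-defensin copies are not. Over all libraries this list had an adjusted p of 0.626 in camera with an estimated correlation and of 0.341 in the exact permutation of its score. The enrichment of the other 40 lists did not pass. With DESeq2 run here, leaving out water 1 to 5 in turn gave counts of 12, 265, 42, 18 and 15 genes. Leaving out TDCA 1 to 5 in turn gave 11, 18, 27, 79 and 11. Ang4, Defa24, Defa26, Gstm3, Olfm4 and Ugt2b35, 6 genes, were called whichever single library was left out. In fits added after the data were seen, 0 genes were called without both water 1 and TDCA 5, and 3 with the smooth muscle score as a covariate, 0 of them among the 25. These fits adjusted over 41999 and 42989 genes, against 13800 in the fit of all libraries. Without both libraries the DESeq2 log2 fold change was −0.88 for Defa24, −3.22 for Gstm3, −1.03 for Defa26, −0.95 for Ang4 and −1.51 for Olfm4. It was 1.22 for Trdn, 0.54 for Slc8a1 and 0.54 for Sgcd.

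Paneth cell products formed the list with the smallest p. Of 18 tested members 17 were lower and 1, the stress response gene Nupr1, named after its values were seen, was higher, with a mean log2 fold change of −0.66 (camera, preset correlation, adjusted p = 5.84e-10; adjusted p = 0.626 with an estimated correlation). Adjusted over the list alone 7 members passed, and 0 passed over all genes. Ang4 averaged 187 ± 54.0 normalized counts in TDCA against 367 ± 41.3 in water mice, Defa26 37.5 ± 6.50 against 80.6 ± 16.2, and Defa30 1044 ± 270 against 2195 ± 665 (SD, n = 5 each). The list score was −0.33 ± 0.28 in TDCA and 0.33 ± 0.22 in water libraries, and every TDCA library lay below every water library (two-sided exact permutation p = 0.00794, the smallest possible, adjusted p = 0.341 over 43 lists). Fry, tested for change in either direction, gave an adjusted p of 0.00504 and, for change on balance in one direction, 0.118. The list's mean stayed at −0.56 with the smooth muscle score as a covariate (adjusted p = 2.21e-09), a fit added after the data were seen. The α-defensin genes are near-identical copies, and how the authors' counting divided shared reads is not given in the sources used here, so values of single members are uncertain.

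**Figure D1:**
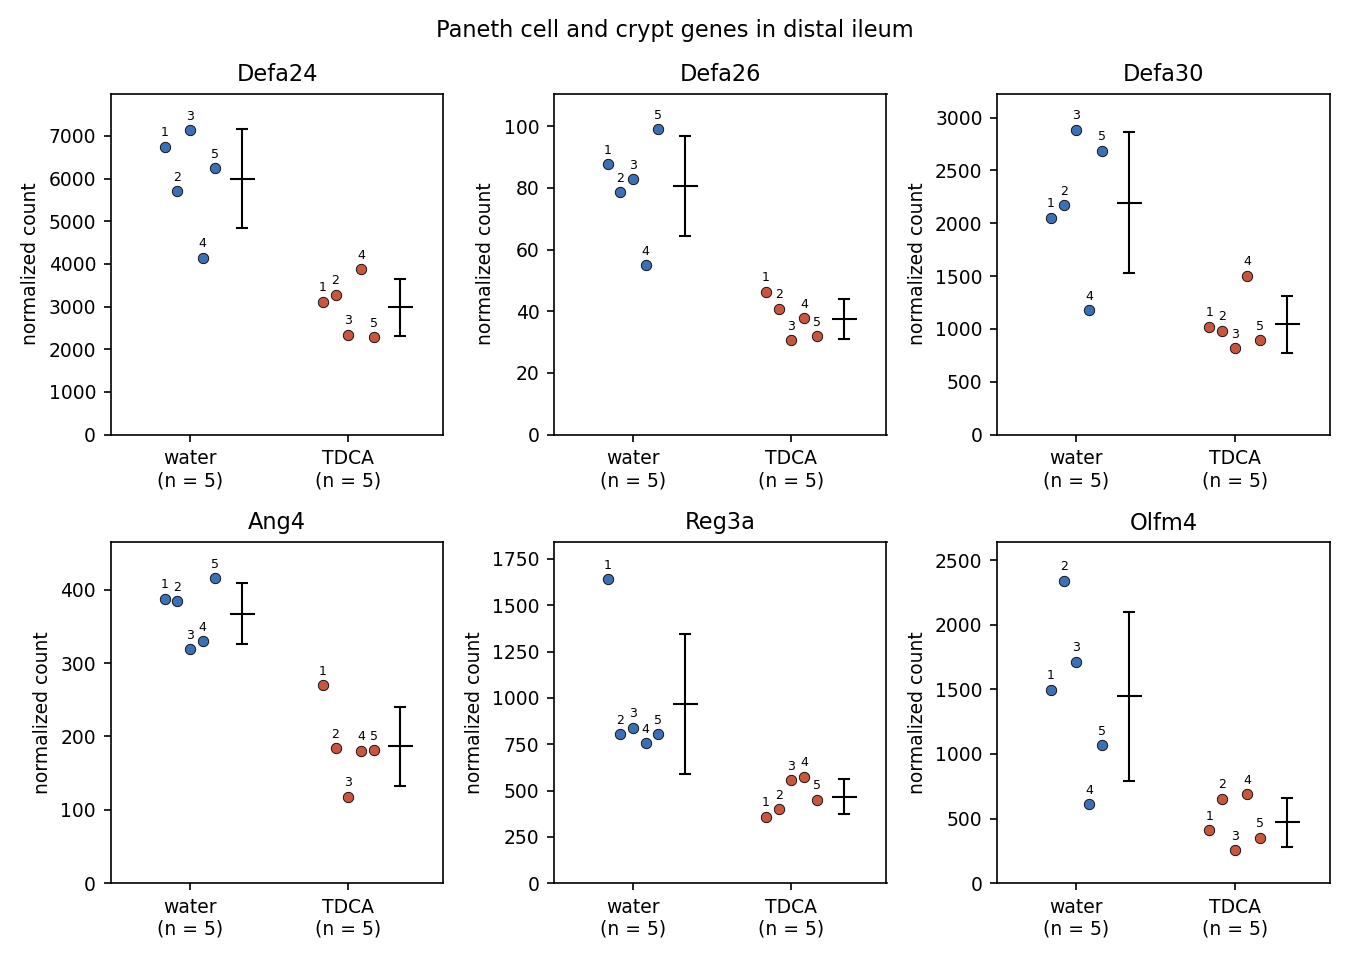
Normalized counts of 6 Paneth cell and crypt genes in water and TDCA libraries; points are single mice numbered by replicate, and bars are the mean ± SD (n = 5 each). For Defa24, Defa26, Ang4 and Reg3a every TDCA mouse lies below every water mouse.

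Other crypt and defence genes differed in direction. Cell-cycle genes were lower, 19 of 20 with 1 higher, with a mean log2 fold change of −0.34 (adjusted p = 2.64e-05; adjusted p = 0.649 with an estimated correlation). Pcna, the DNA polymerase clamp, stood at 493 ± 85.0 normalized counts in TDCA against 754 ± 116 in water mice, and it was the 1 member of that list that passed adjusted over the list alone. Cdk1 (−0.79, SE 0.28), Ccnb1 (−0.62, SE 0.25) and Aurka (−0.49, SE 0.20) did not pass. With the smooth muscle score as a covariate the mean of the list was −0.29 (adjusted p = 1.99e-04). The stem cell list did not pass (mean −0.17, 5 of 11 higher, adjusted p = 0.318), although Olfm4, at 472 ± 190 against 1445 ± 655 normalized counts, passed adjusted over the list alone. Smoc2 in the same list had a log2 fold change of 0.57 (SE 0.28), which turned to −0.04 with the muscle covariate.

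The list of antimicrobial and mucosal defence genes did not pass (mean 0.62, 12 of 17 higher, adjusted p = 0.0549). Its members that passed adjusted over the list alone, 2 in number, went in opposite directions. Reg3a, an antimicrobial lectin gene, was lower at 467 ± 95.2 against 969 ± 377 normalized counts, and Fut2, which adds fucose to epithelial glycans, was higher at 146 ± 77.9 against 47.8 ± 32.3 (SD, n = 5 each). At the preset correlation the list passed without water 3 (mean 0.93), water 5 (0.70), TDCA 2 (0.71) or TDCA 5 (0.76), without both water 1 and TDCA 5 (0.73), and with quantile normalization (0.61), a filter of 50 (0.60), array weights (0.67) or the muscle covariate (1.16, adjusted p = 1.59e-06). Without water 4 its mean was 0.32 (adjusted p = 0.418), and with an estimated correlation over all libraries the adjusted p = 0.649.

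No gene of bile acid handling passed in limma. Fabp6, the bile acid binding protein of ileal enterocytes, averaged 50257 ± 12715 normalized counts in TDCA against 73962 ± 22835 in water mice (log2 fold change −0.55, SE 0.27, adjusted p = 0.473). Fgf15, the hormone that ileal FXR induces, averaged 803 ± 978 against 1081 ± 415 (−1.03, SE 0.65, adjusted p = 0.570), and TDCA 1 alone held 2515 normalized counts while TDCA 2 to 5 held 186 to 708. The uptake transporter gene Slc10a2 had a log2 fold change of 0.36 (SE 0.32). The exporter genes Slc51a (−0.12, SE 0.27) and Slc51b (−0.16, SE 0.26) and the FXR gene Nr1h4 (0.10, SE 0.29) lay near 0, and each turned in sign with a single library left out: Slc51a without TDCA 2 (0.05), Slc51b without TDCA 5 (0.0010) and Nr1h4 without water 1 (−0.0065), water 4 (−0.10) or TDCA 4 (−0.012). The FXR target Nr0b2 (2.84 ± 2.67 against 6.46 ± 5.30) and the bile acid receptor gene Gpbar1 (10.1 ± 5.88 against 5.55 ± 4.13) lay below the filter of the limma test and did not differ beyond chance (exact permutation p = 0.167 and 0.222). As a list, bile acid transport and FXR targets did not pass (mean −0.21, 9 of 12 lower, adjusted p = 0.144), except without TDCA 1 (−0.34, adjusted p = 0.0238). Its members with the smallest p were Osgin1 (−0.57, SE 0.16) and Nos2 (1.01, SE 0.36), and 0 passed adjusted over the list alone.

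**Figure D2:**
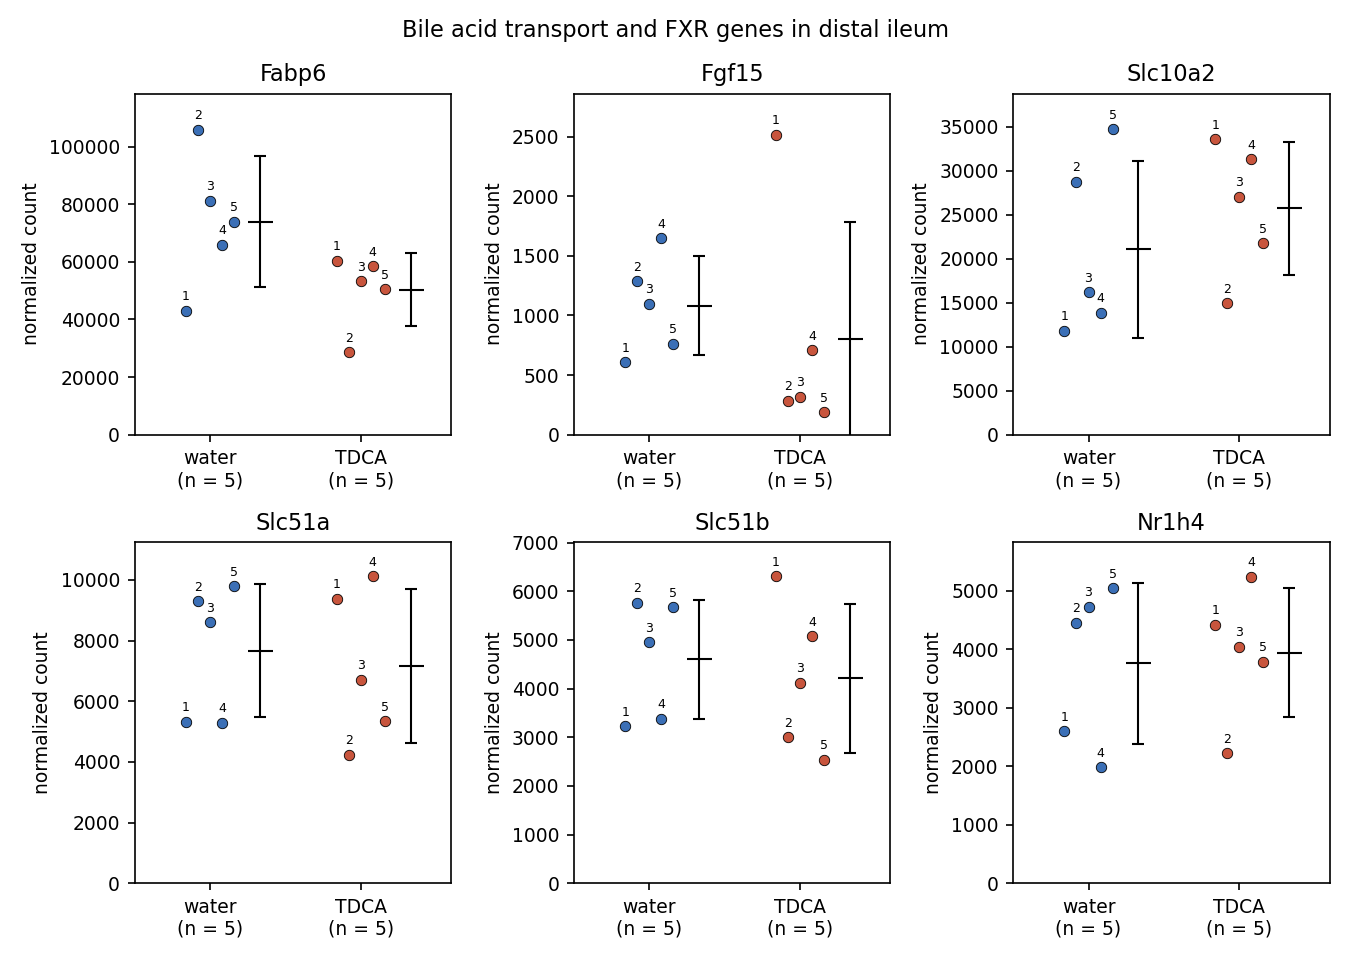
Normalized counts of 6 bile acid transport and FXR genes in water and TDCA libraries; points are single mice numbered by replicate, and bars are the mean ± SD (n = 5 each, the lower bar of Fgf15 ending at the axis). The ranges of the groups overlap for each of these genes.

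Nuclear receptors and detoxification enzymes were lower as lists. Bile acid and nuclear receptors had 10 of 14 members lower (mean −0.21, adjusted p = 0.0150), among them the oxysterol receptor gene Nr1h3 (−0.39, SE 0.14), the vitamin D receptor gene Vdr (−0.37, SE 0.14), Nr5a2 (−0.35, SE 0.15) and Ppara (−0.44, SE 0.22). Targets of PXR, CAR and VDR had 11 of 15 members lower (mean −0.58, adjusted p = 0.00591). For both lists the adjusted p = 0.649 with an estimated correlation, and 0 members passed adjusted over the list alone. Gstm3 averaged 42.3 ± 10.8 normalized counts in TDCA mice against 933 ± 1204 in water mice, where single mice ranged from 48.2 to 2932. Gsta1 averaged 109 ± 52.4 against 700 ± 751, Gstm1 940 ± 340 against 2063 ± 1463, and the carboxylesterase gene Ces2a 2457 ± 949 against 3793 ± 971 (SD, n = 5 each). Targets of the aryl hydrocarbon receptor did not pass as a list (mean −0.16, 5 of 9 lower, adjusted p = 0.487). In that list Nqo1, a quinone reductase gene, passed adjusted over the list alone at 295.6 ± 101.9 against 923.6 ± 492.8 normalized counts, and Cyp1b1 had a log2 fold change of 0.45 (SE 0.34), turning to −0.13 with the muscle covariate. That covariate ended the call of the receptor list (mean −0.12, adjusted p = 0.204) and of the PXR list (−0.07, adjusted p = 0.674), and leaving out both water 1 and TDCA 5 ended the PXR call (−0.25, adjusted p = 0.151). Glutathione S-transferase genes have close copies, so values of single members are uncertain.

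**Figure D3:**
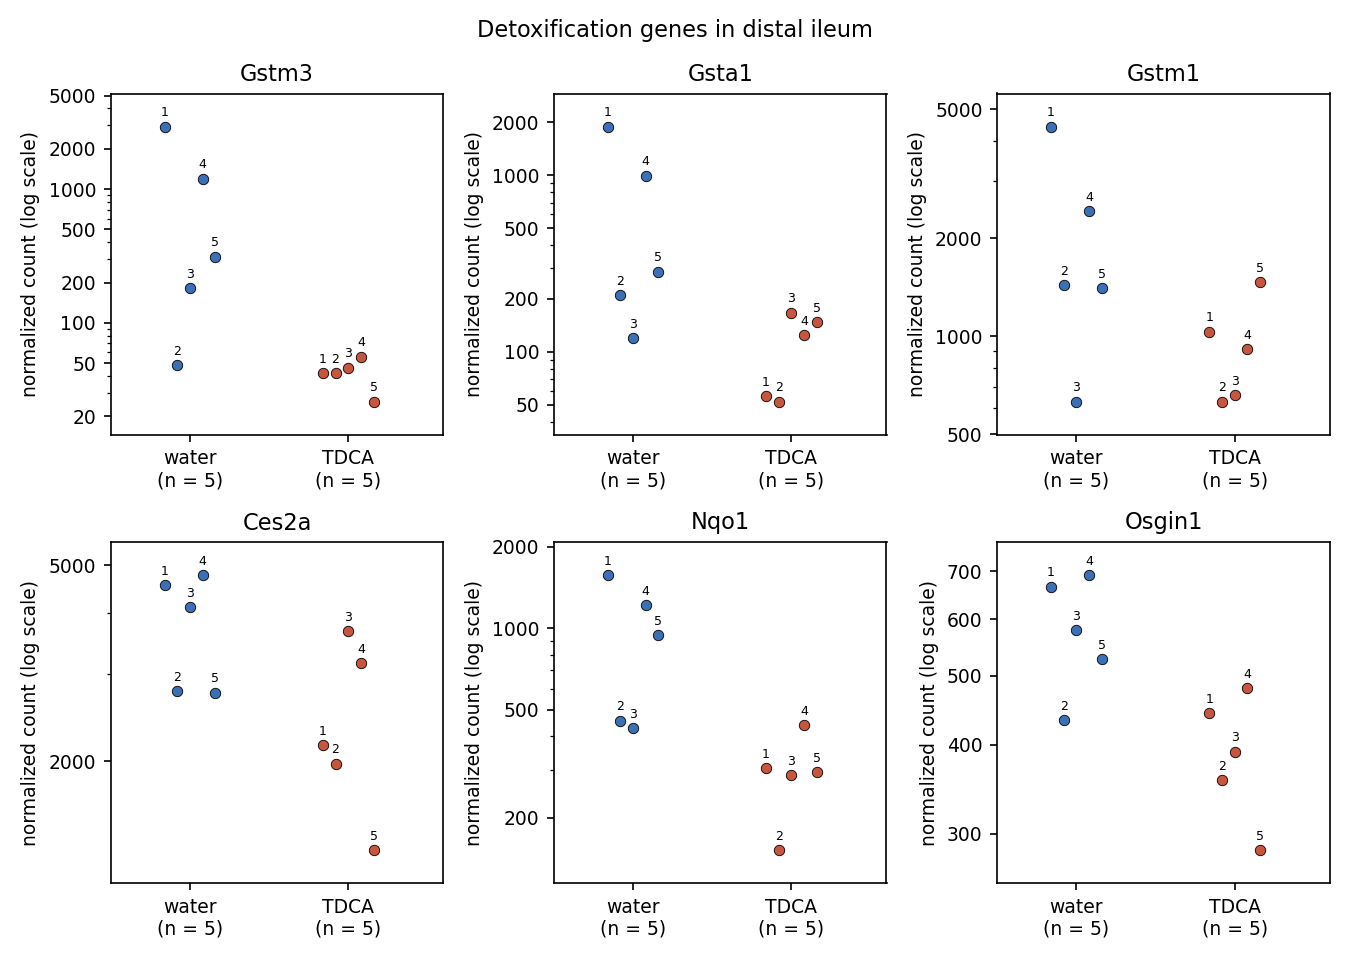
Normalized counts of 6 detoxification genes on log axes in water and TDCA libraries; points are single mice numbered by replicate (n = 5 each). Water 1 and water 4 lie highest among water mice for Gstm3, Gsta1, Gstm1 and Nqo1, and Gstm3 in TDCA mice lies between 25.7 and 55.7.

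Enterocyte programmes were lower as lists. Lipid absorption and chylomicron genes had 22 of 23 members lower (mean −0.41, adjusted p = 2.22e-04), enterocyte markers 14 of 15 (mean −0.35, adjusted p = 0.00513), peptide and amino acid digestion and transport 15 of 16 (mean −0.20, adjusted p = 0.0104) and fatty acid oxidation with PPAR alpha targets 21 of 23 (mean −0.19, adjusted p = 0.0113). For these 4 lists the adjusted p = 0.649 with an estimated correlation, and 0 members passed adjusted over the list alone. Npc1l1, the cholesterol uptake transporter, stood at 10275 ± 3009 normalized counts in TDCA against 16161 ± 1927 in water mice, Apoa1, a main apolipoprotein of chylomicrons, at 164285 ± 33083 against 229697 ± 39778, and the alkaline phosphatase gene Alpi at 8352 ± 2181 against 11668 ± 862 (SD, n = 5 each). Mogat2 (−0.49, SE 0.17) and Dgat1 (−0.45, SE 0.18), both of triglyceride synthesis, and Treh (−0.51, SE 0.26) did not pass. Among peptidases, log2 fold changes were −0.43 for Mep1a, −0.32 for Enpep and −0.26 for Anpep. Among oxidation genes, log2 fold changes were −0.45 for Hadh, −0.37 for Cpt2 and −0.33 for Ucp2.

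With the smooth muscle score as a covariate these calls ended for lipid absorption (mean −0.13, adjusted p = 0.209), enterocyte markers (−0.23, adjusted p = 0.156), peptide digestion (−0.04, adjusted p = 0.388) and fatty acid oxidation (0.05, adjusted p = 0.984). Without both water 1 and TDCA 5 they ended too, with means of −0.09, −0.11, −0.02 and −0.06. Without TDCA 5 alone the enterocyte (−0.15, adjusted p = 0.0665), peptide (−0.07, adjusted p = 0.140) and oxidation (−0.10, adjusted p = 0.0587) calls ended, the last also without water 3 (−0.14, adjusted p = 0.0645) or TDCA 1 (−0.13, adjusted p = 0.0942). Quantile normalization ended the peptide (−0.12, adjusted p = 0.0873) and oxidation (−0.14, adjusted p = 0.0641) calls.

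Among other epithelial lists, enteroendocrine hormones had 15 of 17 members lower (mean −0.34, adjusted p = 0.00513), the unfolded protein response 19 of 21 (mean −0.14, adjusted p = 0.0162) and epithelial junctions 17 of 19 (mean −0.16, adjusted p = 0.0301). For these 3 lists the adjusted p = 0.649 with an estimated correlation, and 0 members passed adjusted over the list alone. The neurotensin gene Nts averaged 2307 ± 763 against 3335 ± 649 normalized counts, Tph1, of serotonin synthesis, 132 ± 45.4 against 179 ± 8.51, Neurod1 had a log2 fold change of −0.60 (SE 0.25) and Chgb of −0.46 (SE 0.24). Log2 fold changes were −0.40 for Sdf2l1, −0.26 for Pdia6 and −0.25 for Hyou1, all chaperone genes, and −0.22 for the asparagine synthetase gene Asns. Among junction genes they were 0.81 (SE 0.33) for Cldn1, −0.49 for Cldn15 and −0.38 for Cdh1. With the muscle covariate the calls ended for enteroendocrine hormones (−0.21, adjusted p = 0.146), the unfolded protein response (0.08, adjusted p = 0.412) and junctions (0.02, adjusted p = 0.837). The unfolded protein response call also ended without water 1 (−0.08), water 5 (−0.08) or TDCA 5 (−0.04), with quantile normalization (−0.10) and without both water 1 and TDCA 5 (0.02). The junction call ended without water 2 (−0.16), water 3 (−0.07), TDCA 2 (−0.12) or TDCA 5 (−0.08), without both water 1 and TDCA 5 (−0.09), and with quantile normalization (−0.11), a filter of 50 (−0.16) or array weights (−0.09).

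Goblet cell (mean −0.15, 10 of 14 lower, adjusted p = 0.0932), sugar digestion (−0.20, 9 of 15 lower, adjusted p = 0.326), cholesterol biosynthesis (−0.10, 17 of 25 lower, adjusted p = 0.133) and M cell genes (0.12, 7 of 10 higher, adjusted p = 0.359) did not pass. With 1 library left out, goblet cell genes passed without water 4 (−0.27), TDCA 3 (−0.21) or TDCA 4 (−0.26), sugar digestion without TDCA 2 (−0.40), cholesterol biosynthesis without water 1 (−0.14), water 4 (−0.15), TDCA 3 (−0.14) or TDCA 4 (−0.19), and M cell genes without water 5 (0.36). Sugar digestion turned to 0.06 without TDCA 5 and 0.20 without both water 1 and TDCA 5, M cell genes to −0.011 without water 1 and −0.07 without both, and with the muscle covariate the means were 0.18 for sugar digestion, 0.099 for goblet cell and −0.13 for M cell genes. Tuft cell genes did not pass either (adjusted p = 0.948), and their mean (−0.02) and the direction of the test (lower) differed in sign from their median (0.0083, 7 of 13 higher), with the direction turning without water 3 (−0.0092), water 5 (0.06), TDCA 2 (0.06) or TDCA 5 (0.04).

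Interferon response genes were higher as lists and class I antigen presentation genes lower. The type I interferon list had 22 of 27 members higher (mean 0.25, adjusted p = 0.00513), the interferon gamma list 17 of 20 (mean 0.29, adjusted p = 0.0144), and macrophage and dendritic cell markers 12 of 17 (mean 0.20, adjusted p = 0.0301). MHC class I presentation had 11 of 14 members lower (mean −0.19, adjusted p = 0.0179). For these 4 lists the adjusted p = 0.649 with an estimated correlation, and 0 members passed adjusted over the list alone. The interferon-induced genes Ifit2 (311 ± 42.7 against 201 ± 74.3 normalized counts), Ifit3 (0.64, SE 0.29), Herc6 (0.41, SE 0.18) and Dhx58 (0.39, SE 0.20) were examples, with the guanylate-binding protein genes Gbp4 (0.52, SE 0.21), Gbp7 (0.44, SE 0.23) and Gbp3 (0.50, SE 0.27) and the GTPase gene Tgtp1 (0.65, SE 0.36). Of the myeloid markers, the growth factor receptor gene Csf1r had a log2 fold change of 0.36 (SE 0.18), Mrc1 of 0.32, Clec9a of 0.48 and Xcr1 of 0.78. B2m, the light chain of class I molecules, averaged 8342 ± 1814 against 11322 ± 2532, and Erap1 1957 ± 318 against 2461 ± 156 (SD, n = 5 each); H2-T3 and Psmb10 were both at −0.26.

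These immune calls depended on single libraries. The type I interferon call ended without water 1 (mean 0.12, adjusted p = 0.0832) or TDCA 1 (0.11, adjusted p = 0.202), and the interferon gamma call without water 1 (0.15, adjusted p = 0.136), water 3 (0.18, adjusted p = 0.0839) or TDCA 1 (0.17, adjusted p = 0.195), or without both water 1 and TDCA 5 (0.16, adjusted p = 0.171). The class I call ended without water 3 (−0.15, adjusted p = 0.0793) or TDCA 5 (−0.08, adjusted p = 0.131) and with quantile normalization (−0.15, adjusted p = 0.0641). The myeloid call ended without water 1 (0.18), water 3 (0.18), TDCA 2 (0.11), TDCA 3 (0.16) or TDCA 5 (0.18), without both water 1 and TDCA 5 (0.16), and with quantile normalization (0.13) or array weights (0.13). With the muscle covariate the 4 calls ended, with means of 0.10 for type I interferon, −0.11 for interferon gamma, −0.15 for class I and 0.10 for myeloid genes.

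Lymphoid and other immune lists did not pass. The MHC class II list had 11 of 13 members higher (mean 0.19, adjusted p = 0.343), B cell and germinal centre genes 16 of 17 (0.33, adjusted p = 0.303), plasma cell and immunoglobulin constant genes 11 of 12 (0.33, adjusted p = 0.188), and natural killer and innate lymphoid genes 6 of 9 (0.20, adjusted p = 0.343). T cell genes had a mean of 0.03 and a test direction of higher, against a median of −0.0047 with 10 of 19 lower (adjusted p = 0.748). Inflammatory cytokines had 3 of 5 tested members lower (−0.11, adjusted p = 0.778), and the list of mast cells, eosinophils and neutrophils had 2 of 3 higher (0.12, adjusted p = 0.487). With 1 library left out, MHC class II passed without water 5 (0.53), B cell genes without water 5 (1.05) or TDCA 3 (0.80), and plasma cell genes without water 5 (0.48) or TDCA 3 (0.47). Other libraries left out turned the direction: MHC class II without water 1 (−0.011), B cell genes without water 1 (−0.14) or water 3 (−0.06), and T cell genes without water 3 (−0.03), water 4 (−0.12) or TDCA 1 (−0.15). Without both water 1 and TDCA 5 the means were −0.09 for MHC class II and −0.47 for B cell genes. The test of inflammatory cytokines turned in direction without water 5 (−0.07), TDCA 4 (0.02) or TDCA 5 (−0.0047). Adjusted over the list alone, 0 members of these lists passed. In the B cell list Ccr6 stood at 26.0 ± 16.4 against 36.7 ± 54.9 normalized counts with a log2 fold change of 0.63 (SE 1.05) that turned to −0.53 in edgeR, −0.50 in DESeq2, −0.23 with array weights and −0.06 without water 3, and S1pr2 was at 0.20 (SE 0.25). Immunoglobulin constant genes have near-identical copies, so values of single members are uncertain.

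In the main fit over all 10 libraries, smooth muscle genes had the highest mean of the lists tested. All 15 smooth muscle genes were higher (mean 0.70, adjusted p = 5.77e-09), with 13 of 15 fibroblast and stroma genes (mean 0.30, adjusted p = 0.00168), 9 of 10 genes of enteric glia and interstitial cells of Cajal (mean 0.56, adjusted p = 6.18e-04), 15 of 17 enteric neuron genes (mean 0.38, adjusted p = 0.00484) and 10 of 14 endothelial and lymphatic genes (mean 0.18, adjusted p = 0.0160). For these 5 lists the adjusted p = 0.649 with an estimated correlation, and 0 members passed adjusted over the list alone. The actin-binding gene Synpo2 averaged 13362 ± 3367 against 8143 ± 3212 normalized counts, Synm 14332 ± 3904 against 8743 ± 3820, Lmod1 2400 ± 604 against 1461 ± 652 and Smtn 2521 ± 464 against 1689 ± 603 (SD, n = 5 each). The glial gene S100b (1.19, SE 0.43) and the interstitial cell genes Kit (0.51, SE 0.19) and Etv1 (0.57, SE 0.19) did not pass. Of the stromal genes, log2 fold changes were 0.41 for Pdgfra, 0.49 for Col6a1, 0.54 for Grem1 and −0.72 (SE 0.32) for Fbln1. The neuronal genes Cartpt (1.06), Elavl4 (0.50) and Stmn2 (0.61) and the endothelial genes Tie1 (0.47), Flt1 (0.50), Cdh5 (0.31) and Pecam1 (0.27) did not pass.

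The smooth muscle score was 0.35 ± 0.34 in TDCA and −0.35 ± 0.69 in water libraries, from −1.22 in water 1 to 0.85 in TDCA 5, and the groups overlapped (two-sided exact permutation p = 0.0952). With this score as a covariate the calls ended for glia (mean 0.02, adjusted p = 0.752), fibroblasts (−0.16, adjusted p = 0.204), neurons (0.21, adjusted p = 0.204) and endothelium (0.09, adjusted p = 0.204). Without both water 1 and TDCA 5 the mean of the muscle list was 0.36, and the fibroblast (0.06, adjusted p = 0.188) and neuron (0.15, adjusted p = 0.188) calls ended. The endothelial call ended without water 3 (0.15, adjusted p = 0.0551), TDCA 2 (0.14, adjusted p = 0.0526) or TDCA 3 (0.12, adjusted p = 0.123).

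**Figure D4:**
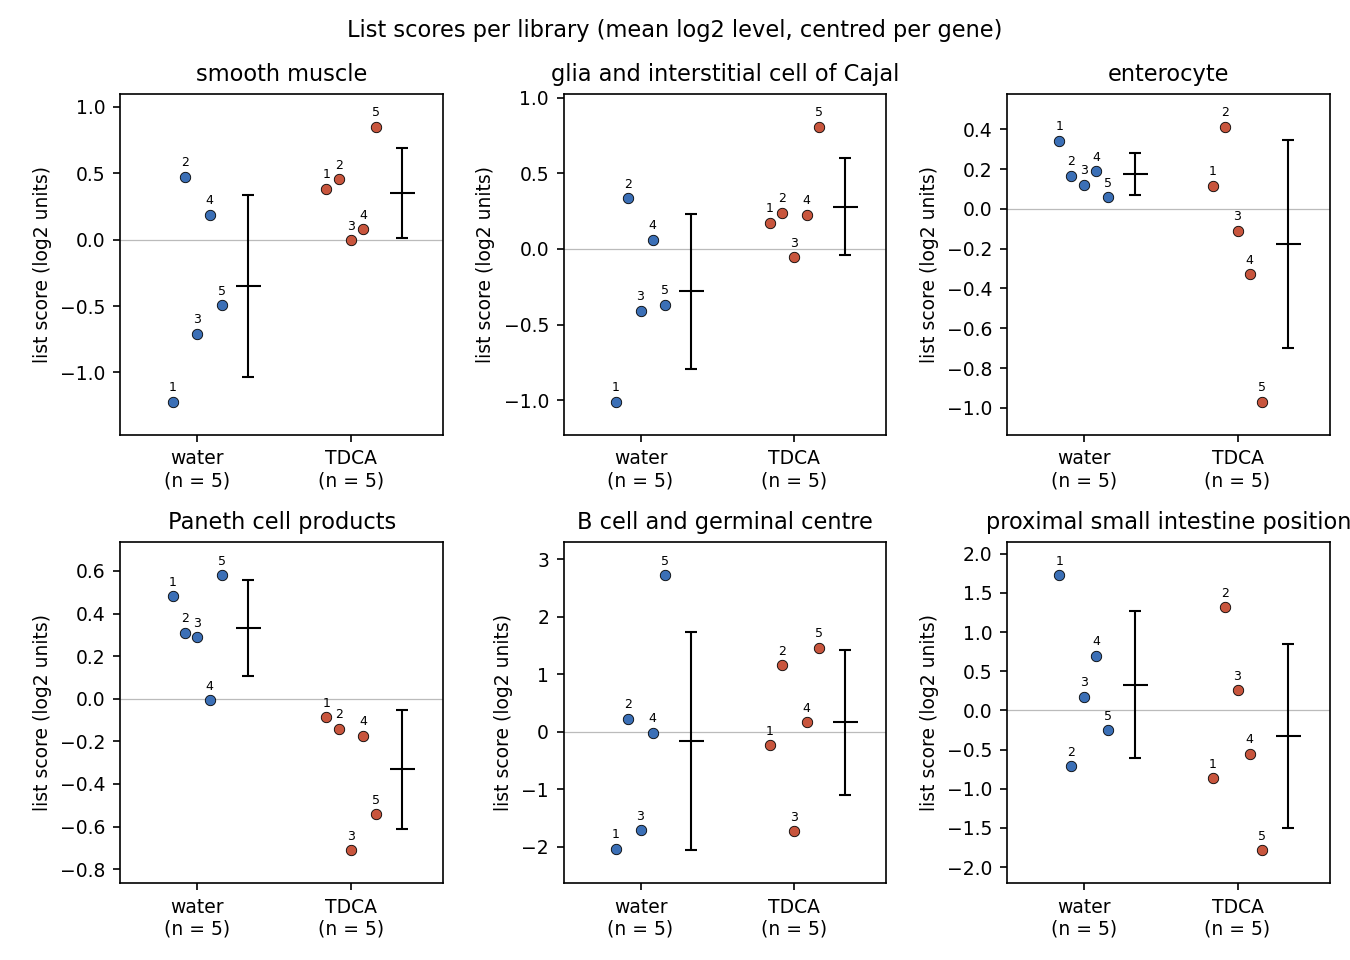
List scores of 6 gene lists in log2 units, the mean log2 level of a list's genes centred per gene; points are single mice numbered by replicate, and bars are the mean ± SD (n = 5 each). Water 1 is lowest and TDCA 5 highest for smooth muscle, and only the Paneth scores of the 6 lists separate the groups.

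Lists for sampling position and tissue state did not pass. Proximal small intestine genes had 12 of 14 members lower (mean −0.65, adjusted p = 0.0508), with Dmbt1 at 0.97 (SE 0.44), and the mean turned to 0.09 with the muscle covariate and to 0.06 without both water 1 and TDCA 5. This list passed without water 2 (−0.91), water 5 (−0.80), TDCA 2 (−1.07) or TDCA 3 (−0.80), while its mean was −0.30 without water 1 and −0.29 without TDCA 5. Ileal and colonic position genes had a mean of 0.25, against a median of −0.16 and a test direction of lower (9 of 12 lower, adjusted p = 0.447). Immediate early genes (mean −0.14, 11 of 17 lower, adjusted p = 0.207) held 1 member that passed adjusted over the list alone, Egr2, named after its values were seen. Circadian clock genes (0.17, 11 of 18 higher, adjusted p = 0.217), mitochondrially encoded genes (−0.08, 12 of 15 lower, adjusted p = 0.359), adipose and mesentery genes (−0.22, 10 of 14 lower, adjusted p = 0.465) and erythrocyte genes (−0.48, 4 of 4 lower, adjusted p = 0.111) did not pass, the last passing with the muscle covariate (−0.94, adjusted p = 7.02e-04), with array weights (−0.72) and without both water 1 and TDCA 5 (−0.79). With 1 library left out, immediate early genes passed without water 1 (−0.17), water 4 (−0.26) or TDCA 1 (−0.23), circadian genes without TDCA 5 (0.31, and 0.38 without water 1 too), mitochondrially encoded genes without water 3 (−0.28), adipose genes without TDCA 3 (−0.45) and erythrocyte genes without TDCA 5 (−0.70). The mean turned to 0.04 for mitochondrially encoded genes without water 4 and to 0.02 for adipose genes without water 2, and the test of adipose genes also turned in direction without TDCA 2 (−0.04), as did that of ileal and colonic position (0.44). The pancreas list had under 3 members above the filter and was not tested.

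Of the 43 lists tested, 20 passed camera with the preset correlation, 8 higher and 12 lower. With an estimated correlation 0 passed, the smallest adjusted p being 0.626, with 2 at an unadjusted p under 0.05. Fry on balance in one direction passed 0, and the exact permutation of list scores passed 0, with 3 at an unadjusted permutation p under 0.05: Paneth cell products (0.00794), enteroendocrine hormones (0.0238) and bile acid and nuclear receptors (0.0317). Counting also lists that had not passed in the main fit, 12 passed without both water 1 and TDCA 5, and 4 with the smooth muscle score as a covariate. Paneth cell products, proliferation and smooth muscle, 3 lists, passed in every camera fit to which they were put other than that with the estimated correlation. For 3 lists that passed, the median lay within the middle 95% of 10000 lists matched on transcript length and level: fatty acid oxidation (percentile 11.7), the unfolded protein response (12.9) and endothelium (96.4).

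**Figure D5:**
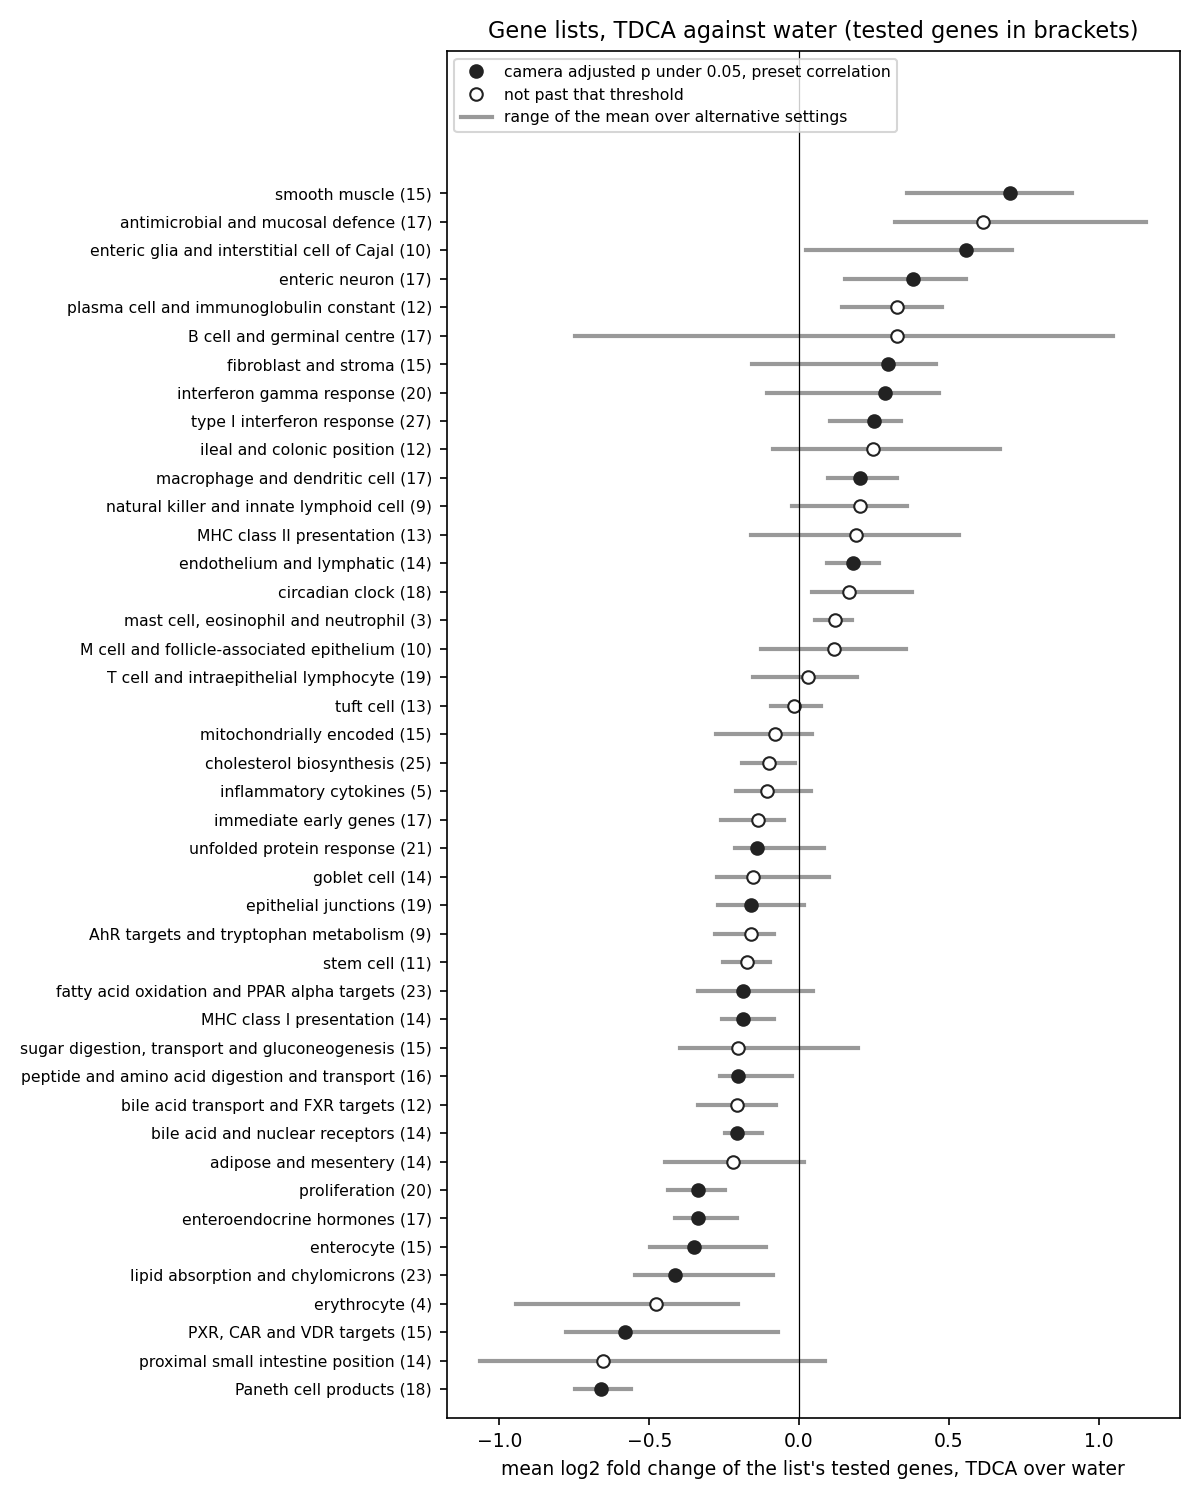
Mean log2 fold change of TDCA over water for the tested genes of 43 lists, their number in brackets; filled points passed camera with the preset correlation, and grey bars span the mean over alternative settings. Paneth cell products lie at −0.66 and smooth muscle at 0.70.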

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

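The tests of the smooth muscle score against the glia score and against the first principal component were chosen after the results were seen. In a group of 5, a library is named here where its gap to the next library exceeded Dixon's 95% critical ratio to the group's range. Of 316 values looked at, 17 did so, and chance gives 15.8. TDCA 5 was the library that stood apart in 8 of them. In log2 level it was highest for Pappa (0.719 of the range), Dnah5 (0.840), Etv1 (0.844) and S100b (0.845) and lowest for Alpi (0.804). In list score it was lowest for the unfolded protein response (0.825) and the circadian clock (0.801) and highest for fibroblast and stroma (0.796). TDCA 4 was lowest for Ifit2 (0.764) and Gbp7 (0.860), TDCA 2 for Fabp6 (0.762) and water 4 for Asns (0.837), and water 1 was highest for Reg3a (0.867). TDCA 3 was highest in the score of mitochondrially encoded genes (0.757) and lowest in that of stem cell genes (0.729). Water 3 was highest in the score of ileal and colonic position (0.723) and lowest in the share of reads on mitochondrial ribosomal RNA (0.849), at 30.2% against 45.4% in the next water library.

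Smooth muscle genes were higher in TDCA libraries by a mean log2 fold change of 0.70, and a trend with transcript length is argued against by a list median at percentile 100 of 10000 lists matched on length and level. A candidate explanation is that the TDCA pieces held more muscle wall: with group means removed, the smooth muscle score followed the score of glia and interstitial cells, with which it shares 0 genes (Pearson r = 0.961, permutation p = 4.7e-04, Spearman rho = 0.927, permutation p = 0.00189, each unchanged by adjustment over 2 relations). Without the 2 libraries farthest from the median the Pearson r was 0.902. Whether water 1 and TDCA 5 alone made the difference stays open, since without them it was 0.362 (exact permutation p = 0.343, smallest possible 0.0286). An effect of TDCA on the muscle layer itself also stays open and was not tested.

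When the 10 libraries were divided into 5 and 5 in other ways, 100 of the 126 possible splits being drawn with the real one included, 4 counts were compared. For limma's 0 genes in the real split the comparison can say nothing, since all 100 splits must give a count as large (highest other 1). Chance could not be excluded for the other counts. Limma gave 1919 genes at an unadjusted p under 0.05 in the real split, 7 splits gave as many, and the highest other count was 3249. Camera passed 20 lists in the real split, 17 splits gave as many, and the highest other count was 22. DESeq2 called 25 genes in the real split, 19 splits gave as many, and the highest other count was 775. The split with 775 genes set water 1, water 3, water 4, water 5 and TDCA 3 against the rest, so that it differs from the real split only by an exchange of water 2 and TDCA 3. These are the 5 lowest libraries along the first principal component, and the count points to a structure of the samples, in which a part of the treatment was not separated from other differences. That component was correlated with the smooth muscle score (Pearson r = 0.905, permutation p = 2e-04, adjusted p = 4e-04). Spearman rho was 0.891 (permutation p = 0.00137, adjusted p = 0.00189), and Pearson r was 0.740 without the 2 farthest libraries. The component was computed from all tested genes, muscle genes included, and group means were not removed. The 2 measures are thus not independent, which the permutation does not allow for.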

How the results depend on the processing

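Fits without water 1 and TDCA 5, fits with the smooth muscle score as a covariate, the exact permutation of list scores and DESeq2 with libraries left out were chosen after the results were seen. The count of 0 genes in limma was the same under every pseudocount, filter, normalization, moderation and weighting tried, with each library left out, and in edgeR and limma-voom (unadjusted counts from 1143 to 2579), and it was 0 without both water 1 and TDCA 5 (928 unadjusted) and with the muscle covariate (677 unadjusted), while DESeq2 called 25. DESeq2 called 11 to 265 genes with a single library left out, 0 without both water 1 and TDCA 5 (adjusted over 41999 genes), and 3 with the muscle covariate (over 42989 genes). The authors' table holds 64 genes at an adjusted p under 0.10. The count of passing lists, 20 in the main fit, was 0 with an estimated correlation and 0 with the exact permutation of scores. Fry passed 0 on balance in one direction and 1 for change in either direction. The count was 12 without water 1 and TDCA 5 and 4 with the muscle covariate. It was 15 with quantile normalization and 16 to 25 with a single library left out. The cause was not tested. These counts include lists that had not passed in the main fit. With the muscle covariate, antimicrobial and erythrocyte genes were such lists, and Paneth cell products and proliferation were the others. Same-numbered libraries of the groups did not deviate together (correlations −0.06, −0.14, 0.08, −0.15 and 0.17 by the numbers in the descriptions, −0.06, −0.14 and 0.27 by those in the titles), and with the replicate block 0 genes and 24 lists passed, with 0 genes for the block on title numbers. By description only water 5, and by title only the pair of water 3 and TDCA 4, correlated best with its own number. Over all alternatives, 2559 values of named genes kept direction and side of the threshold, 13 passed only in DESeq2 and 21 changed sign, over 10 of 104 genes; of list values 650 kept both, 43 passed where they had not, 120 no longer passed and 44 changed direction in the test. Genes below the filter of 10 normalized counts in 5 libraries entered only the fits without it.

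The values whose direction in their test changed follow as log2 changes, and the cause was not tested. With the muscle covariate the mean was −0.16 for MHC class II, −0.11 for interferon gamma, −0.058 for inflammatory cytokines, 0.18 for sugar digestion, 0.016 for junctions, 0.083 for the unfolded protein response, 0.087 for proximal position, 0.67 for ileal and colonic position, 0.099 for goblet, 0.072 for tuft, −0.75 for B cell, −0.13 for M cell and −0.16 for fibroblast genes, and the fold change was −0.0019 for Gbp7, −0.047 for Gbp3, −0.13 for Cyp1b1, 0.013 for Hyou1, −0.040 for Smoc2, −0.15 for S1pr2 and −0.75 for Ccr6. Without water 1 and TDCA 5 it was −0.089 for MHC class II, 0.041 for cytokines, 0.20 for sugar digestion, 0.061 for proximal position, 0.011 for tuft, −0.47 for B cell and −0.073 for M cell genes, −0.0058 for Nr1h4, −0.058 for S1pr2 and −0.14 for Ccr6. Array weights gave −0.15 for MHC class II, −0.45 for B cell genes and −0.23 for Ccr6. A filter of 50 gave 0.030 for cytokines and −0.0043 for tuft genes. Quantile normalization gave −0.068 for T cell genes. For Ccr6, edgeR gave −0.53 and DESeq2 −0.50. The block on title numbers gave 0.021 for Slc51b and −0.029 for Nr1h4. For ileal and colonic position the score gave 0.25 where camera's direction was lower. With a single library left out the mean ran from −0.011 to 0.53 for MHC class II, −0.21 to 0.024 for cytokines, −0.40 to 0.056 for sugar digestion, −0.28 to 0.045 for mitochondrially encoded, 0.028 to 0.45 for ileal and colonic position, −0.094 to 0.063 for tuft, −0.15 to 0.19 for T cell, −0.14 to 1.05 for B cell and −0.45 to 0.017 for adipose genes, and the fold change from −0.27 to 0.046 for Slc51a, −0.33 to 0.0010 for Slc51b, −0.10 to 0.30 for Nr1h4 and −0.059 to 1.44 for Ccr6. The mean of a list changed sign without its test changing direction or while its call ended for fatty acid oxidation with the muscle covariate (0.045), the unfolded protein response without water 1 and TDCA 5 (0.024), ileal and colonic position (−0.088) and natural killer genes (−0.023) with a filter of 50, and M cell genes with array weights (−0.095) or without water 1 (−0.011).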

Other observations

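The list of 36 genes of antioxidant defence and glutathione metabolism was written after the calls of the authors' table were seen, and the test of Paneth products against other epithelial scores was chosen after the Paneth result was seen. These antioxidant and glutathione genes, which include known targets of the transcription factor NRF2, were lower in TDCA mice as a group. Of 35 tested, 30 were lower and 5 higher, with a mean log2 fold change of −0.78, and 21 passed adjusted over the list alone, which is not independent evidence because of how the list was written. The carbonyl reductase gene Cbr1 averaged 2313 ± 676 normalized counts in TDCA against 6040 ± 2799 in water mice, Tkt, the transketolase of the pentose phosphate pathway, 5628 ± 970 against 8702 ± 907, and Gsr, which reduces oxidized glutathione, 3214 ± 662 against 5957 ± 2642 (SD, n = 5 each). G6pdx, which supplies NADPH, averaged 687 ± 127 against 1117 ± 296, and the peroxiredoxin gene Prdx1 7160 ± 810 against 11199 ± 3449. Gclc, of glutathione synthesis, averaged 2632 ± 638 against 4750 ± 2767 but was not among the 21 (limma, unadjusted p = 0.0938). Gclc stood at 8306 in water 1 and 7046 in water 4. Water 2, 3 and 5 held 1867 to 3279, against 1873 to 3523 in TDCA libraries. Hmox1 (log2 fold change 0.23) and Slc7a11 (0.05), also NRF2 targets, were not lower. These genes were named after their values were seen. The list score was −0.39 ± 0.13 in TDCA and 0.39 ± 0.56 in water libraries (two-sided exact permutation p = 0.0159), and the score difference was −0.67 without the 4 members called in the authors' table (exact permutation p = 0.0238). Of the members, 3 also belong to the PXR, CAR and VDR list.

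Lower expression of the antioxidant and glutathione list in TDCA mice was set against 4 technical explanations. With the score of proximal small intestine genes as a covariate the score difference was −0.713 (permutation p = 0.0317), against −0.783 without it. For the members not called in the authors' table it was −0.610 with that covariate (permutation p = 0.0476). With the smooth muscle score as a covariate the difference was −0.589 (permutation p = 0.0397), and −0.519 for the members not called (permutation p = 0.0476). These permutations moved the group labels with the covariate held fixed, so they ignore the link between group and covariate. The difference kept its direction, but a more proximal position of the water pieces and more muscle in the TDCA pieces stay open. A trend with length alone is argued against by a list median at percentile 0 of 10000 lists matched on length and level. Genes of those lists were drawn independently of each other, so this comparison does not weigh chance. Whether water 1 and water 4 alone made the difference cannot be told apart from an effect of TDCA: without both it was −0.428 (exact permutation p = 0.0357, smallest possible 0.0179), but −0.348 for the members not called (exact permutation p = 0.0536), and water 3 (−0.24) lay above only 4 of the 5 TDCA libraries. Chance stays open too, since the list was written on these samples.

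Paneth products, a list fixed in advance, were lower in TDCA mice. Less mucosa in the TDCA pieces is argued against, because the Paneth score differed by −0.488 relative to the mean of the enterocyte, goblet and tuft scores (exact permutation p = 0.00794, the smallest possible), which themselves differed by −0.17 (exact permutation p = 0.238), though against enterocytes alone the difference was −0.31 with overlapping groups (exact permutation p = 0.183; −0.51, p = 0.0397, against goblet and −0.64, p = 0.00794, against tuft cells), so a loss shared with enterocytes stays open. A trend with transcript length alone is argued against by a list median at percentile 0 of 10000 matched lists, whose middle 95% ran from −0.30 to −0.01. Genes of the matched lists were drawn independently of each other, so this comparison does not weigh chance. Reads moved among the 39 α-defensin genes with a Defa symbol are argued against by their sum. It was 18172 ± 6929 normalized counts in TDCA against 29743 ± 3668 in water mice (SD, n = 5 each, log2 ratio −0.791, exact permutation p = 0.0159). The sum leaves out any copy under another symbol and any shared reads that the counting dropped, so those stay open. Chance stays open over the 43 lists (exact permutation, adjusted p = 0.341), and whether there may be fewer Paneth cells or less mRNA in each was not tested.

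Of the 20 lists that passed camera, 17 had a median outside the middle 95% of lists matched on length and level, as did 27 of all 43. For the other 3, fatty acid oxidation, the unfolded protein response and endothelium, the trend with transcript length stays open. Since genes of the matched lists were drawn independently, a list whose genes vary together can lie outside without any effect of TDCA.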
